A study of Mus with 8 samples.

How the data were processed

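Total RNA of 8 whole subcutaneous Pan02 tumours, 4 from Control and 4 from Mutant hosts, was measured on Agilent mouse expression arrays in 1 colour. Per the labels' protocols, RNA was extracted with a Maxwell RSC simplyRNA tissue kit, and cRNA was amplified and labelled with Cy3 from 0.5 ug of RNA. Per the file headers, intensity values came from Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.1. All arrays lay on 1 slide with 1 scan, in 2 rows that each held 2 Control and 2 Mutant tumours. The processed signal is, per the file headers, the spot intensity after subtraction of background and spatial detrending within the array, and it was deposited on a linear scale with no scaling between arrays. The flag columns that the authors deposited beside it carry no unit of measurement (other). The authors' deposited value table holds intensity too, on a linear scale: for 99.484% to 99.505% of probes it equals, within 0.01%, the mean processed signal of the probe's spots on the same array. Its column medians, 52.4 to 61.2, show no scaling or centring between arrays, and no ratio or direction is involved. Probes' gene names come from the RefSeq accession in the scanner files, matched without version to a gene table of assembly GRCm38.p6. This gave 1 gene for 32994 of 56605 probes (58.3%), several genes for 0 and none for 23611, of which 7284 carry an Ensembl transcript accession. The array design names another assembly, so no coordinates are given.

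Spots flagged as outliers, 66 to 117 per array, were left out, spots of a probe were averaged, and control spots were removed. Log2 of the processed signal was centred on the 75th percentile of each array, which lay between 575.9 and 740.7 before log transformation. Probes well above background on at least 4 of 8 arrays were kept (36824, of which 13335 had no gene name here), and each gene was represented by the probe with the highest mean over the 8 arrays, leaving 16068 genes. For 7899 of 22911 genes the array carries several probes. Groups were compared with limma 3.58.1 in R 4.3.3, with the group as the only term, and adjusted p-values follow Benjamini and Hochberg. Single values were also compared by two-sided exact permutation over the 70 arrangements of the tumours, where the smallest p is 0.0286. Arrays give no count depth, and precision rests on 4 tumours per group. The design text gives 4 mice per group, and tumours were treated as independent.

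The 23 pathway and 20 cell type lists, the named genes' rule, the main settings and most alternatives were fixed before the data were examined. Lists with at least 5 measured genes (42 of them) were tested by camera with a preset correlation of 0.01, with an estimated correlation, by fry, whose p asks whether a list's genes move on balance 1 way without comparing them with other genes, and by ranks. A list level is the mean log2 signal of its measured genes, each centred on its mean over the tumours. X-inactivation and Y-linked genes had too few measured members for a test. Named genes are Ext1, S100a4, in each direction up to 10 genes past the adjusted threshold or, since none passed, those of smallest unadjusted p with at least a 2-fold difference and no overlap of the groups, and up to 4 members of smallest p in each list described. Predicted models without a gene name proper were counted but not named, and 10 higher and 4 lower genes met the rule, of which 1 lower gene is not described. Members of a list named beyond these (Eno3, and Vegfa where the hypoxia list is described) were chosen after their values were seen. Where a probe was not well above background on any array of a group, a fold is given as a bound, from the mean of the bright group against, per array, the higher of the lowest signal among probes well above background and the probe's own.

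Alternatives covered background correction by normexp (offset 50), quantile normalization, median centring, 3 other filters on dim probes, the mean of a gene's probes, every probe tested by itself, the deposited value table, a variance trend, array weights, the replicate number and the slide row as blocks, and leaving out each tumour. The plan named mean spot signals for normexp, but the scanner columns used here hold medians, so it ran on the median spot and background signals. The Xist level and the muscle list level as covariates were added after the data were seen. The pipeline was tested on simulated data with the means and residual SDs of the 16068 genes and 200 changed genes in each of 20 draws. Of 2-fold changes 50.6% were recovered, of 4-fold changes 80.0% and of 8-fold changes 88.5%, and 4.7% of calls were false. A shift of 0.5 in a list was called in 20 of 20 draws. The simulated genes varied independently, unlike genes of a real list. Tables were handled with Python 3.11.15 and pandas 2.3.3.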

Results

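Gene expression was measured in 8 subcutaneous tumours that grew from transplanted Pan02 cells, a mouse pancreatic cancer cell line. Wild-type hosts, called Control, carried 4 of the tumours, and the other 4 grew in hosts called Mutant, in which Ext1 alleles flanked by loxP sites were combined with a Cre recombinase under S100a4 control. Ext1 encodes an enzyme that elongates heparan sulfate chains, and S100a4 is expressed by fibroblasts and by some other stromal cells. The comparison of the groups asks how whole tumours differ when host cells of this lineage lose the enzyme, while the transplanted cells keep it. Tumours were taken 36 to 40 days after transplantation, and RNA of each was hybridised to 1 Cy3 array. Between 61.5% and 67.2% of the 56605 probes were well above background on an array, and no spot was saturated. Levels below are log2 signals relative to the 75th percentile of the array, differences are Mutant minus Control, and the number of arrays limits their precision.

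Tumours in Mutant hosts held about as much Ext1 transcript as tumours in Control hosts. The Ext1 probe read 3.07 ± 0.76 in Control tumours and 3.15 ± 0.22 in Mutant tumours (SD, n = 4 each), a difference of 0.07 with a standard error of 0.36 (two-sided exact permutation p = 0.943). Control 4 had the lowest Ext1 level, 2.02, and without it the difference was -0.28. The sign of the Ext1 difference also turned without Mutant 3, to -0.02, and with arrays weighted by their scatter, to -0.11. Whether the Ext1 probe lies in the deleted part of the gene is not known here, and the cancer cells carry intact Ext1, so the probe checks neither the deletion nor the labels. S100a4, whose control regions drive the recombinase but which cancer cells in a mesenchymal state also express, was at 8.19 ± 0.54 in Control and 8.43 ± 0.35 in Mutant tumours (SD, n = 4 each; difference 0.24, two-sided exact permutation p = 0.486).

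The heparan sulfate machinery as a group did not stand apart between the hosts. Among 22 measured genes of chain synthesis and modification the median difference was 0.06, 12 members were above 0 and 10 below, and none passed, either over all genes or adjusted over the list alone (camera adjusted p = 0.825). The member with the smallest p was Ext2, the partner of Ext1 in the chain polymerase. Ext2 was at -3.15 ± 0.13 in Control and -3.43 ± 0.13 in Mutant tumours (SD, n = 4 each), 0.824-fold, with no overlap of the groups (two-sided exact permutation p = 0.0286, the smallest value that 4 against 4 tumours allow; limma adjusted p = 1). The sulfatase Sulf2 differed by 0.26, and the glycosyltransferases Extl3 and Extl2 differed by 0.24 and 0.27. Of 14 proteoglycan core proteins 11 were above 0, with a median of 0.16 (camera adjusted p = 0.514), which was 0.02 without Mutant 2. In this list Cd44 differed by -0.28, Col18a1 by 0.38, Gpc2 by 0.57 and Sdc2 by 1.51, the last with a standard error of 1.21.

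**Figure D1:**
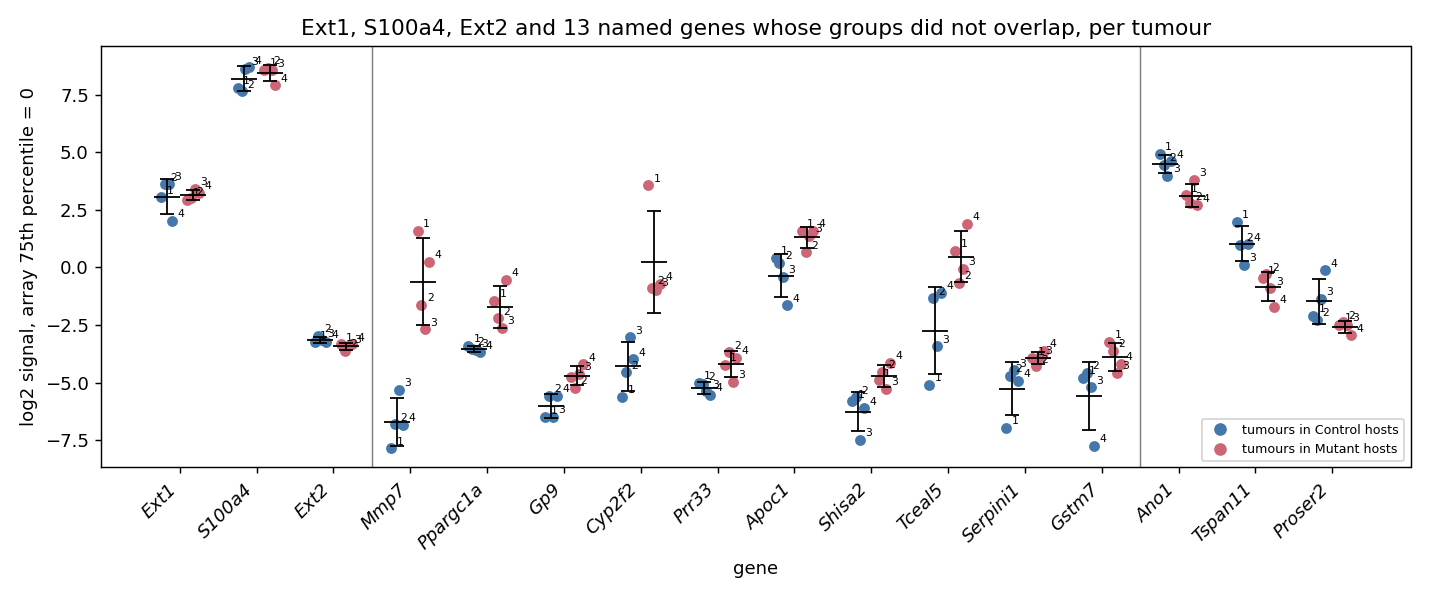
Log2 signal relative to the 75th percentile of the array (vertical axis) for Ext1, S100a4, Ext2 and the 13 genes named for at least a 2-fold difference without overlap (horizontal axis). Points are tumours labelled by replicate number, blue for Control and red for Mutant hosts, and black bars give mean and SD (n = 4). Mmp7 lies between -7.85 and -5.32 in Control tumours and between -2.68 and 1.59 in Mutant tumours, while the Ext1 values of the groups overlap.

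Mmp7, the secreted protease matrilysin, had the smallest p of the 16068 genes tested and separated the groups most widely among the named genes. It was not well above background on any Control array and was above it on all 4 Mutant arrays, at -0.61 ± 1.90 (SD, n = 4), so that Mutant tumours held at least 34.7-fold more. This bound sets the Mutant mean against the lowest signal that counted as above background on the Control arrays, and it was 20.8-fold without Mutant 1 and 55.9-fold without Mutant 3. Cyp2f2, a cytochrome P450 known from airway club cells, was 23.3-fold higher in Mutant tumours, with 3 of 4 Control arrays above background and with Mutant 1, at 3.57, far above the other Mutant tumours. Tceal5 was 9.23-fold higher, Ppargc1a, a coactivator of mitochondrial biogenesis, 3.58-fold, the glutathione transferase Gstm7 3.20-fold, the apolipoprotein Apoc1 3.16-fold and Shisa2 2.93-fold. Serpini1, the protease inhibitor neuroserpin, and Gp9, a subunit of the platelet receptor for von Willebrand factor, were each 2.51-fold higher, and Prr33 was 2.06-fold higher. Single tumours weighed on several of these: the log2 difference was 3.44 in place of 4.54 for Cyp2f2 without Mutant 1, 2.42 in place of 3.21 for Tceal5 and 0.76 in place of 1.33 for Serpini1 without Control 1, and 0.95 in place of 1.68 for Gstm7 without Control 4. Several were dim in Control tumours, where Gp9 was above background on 2 arrays, Shisa2 on 1, and Serpini1 and Gstm7 on 3. Their folds rest in part on signals not well above background, most of all for Shisa2 and Gp9, and may be overstated. Shisa2 was above background on 3 Mutant arrays. On the lower side were the tetraspanin Tspan11 at 0.275-fold, the calcium-activated chloride channel Ano1 at 0.383-fold and Proser2 at 0.461-fold, whose log2 difference was -0.67 in place of -1.12 without Control 4. The groups did not overlap in any of these 13 genes, because the rule that named them required it. This fixes the two-sided exact permutation p at 0.0286 for each, so it is no test of them. None passed the test over all genes (limma adjusted p = 1 for each). A further 4 genes that met the rule were predicted models and are not named.

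Across all 16068 genes, limma called 0 genes higher and 0 lower in Mutant tumours at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 467 genes, 301 of them higher and 166 lower, where chance gives 803. With a tumour left out this count was 972 without Control 2, 195 without Mutant 1, 257 without Mutant 4, 305 without Control 1 and 314 without Mutant 2, and 579 to 659 without the others. Of the 467 genes, 142 differed at least 2-fold, 128 higher and 14 lower. Among the higher ones were 9 skeletal muscle markers of the list fixed beforehand. Muscle genes outside that list were among them too, such as Mybpc2 (4.17), Trim63 (3.55) and Myh8 (3.45), so 9 understates the muscle genes. These further genes come from a list written after the muscle difference was seen. With the muscle list level as a covariate, chosen after the data were seen, 65 genes differed at least 2-fold, 76.9% of them higher. The groups did not overlap in 228 genes, or 1.42%, where chance gives 2.86%. Single tumours moved the 2-fold count, which was 249 without Control 2, 249 without Mutant 3, 50 without Mutant 1, 84 without Mutant 2 and 71 without Mutant 4. No gene was called under any alternative setting.

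Of 42 gene lists fixed beforehand, 2 stood apart by camera with its preset correlation, skeletal muscle markers, which rose, and hypoxia response and glycolysis genes, which fell. Neither call held when the correlation within the list was taken from the data (camera adjusted p = 0.939 with an estimated correlation for both lists) or by fry (adjusted p = 0.993 for both), and ranks called 4 lists, these 2, antigen presentation genes (adjusted p = 0.00709 by cameraPR) and proliferation genes (0.0424). Relabelling the tumours gave calls as readily, since each of the 34 other splits into 4 and 4 called at least 5 lists. With a tumour left out, the number of lists called was 3 without Control 1, 6 without Control 2, 8 without Control 3, 20 without Control 4, 5 without Mutant 1, 5 without Mutant 2, 6 without Mutant 3 and 2 without Mutant 4. With an estimated correlation, camera called 0 lists under any of 23 settings, so each call given below for other settings rests on the preset correlation. No member of any list passed adjusted over the list alone.

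**Figure D2:**
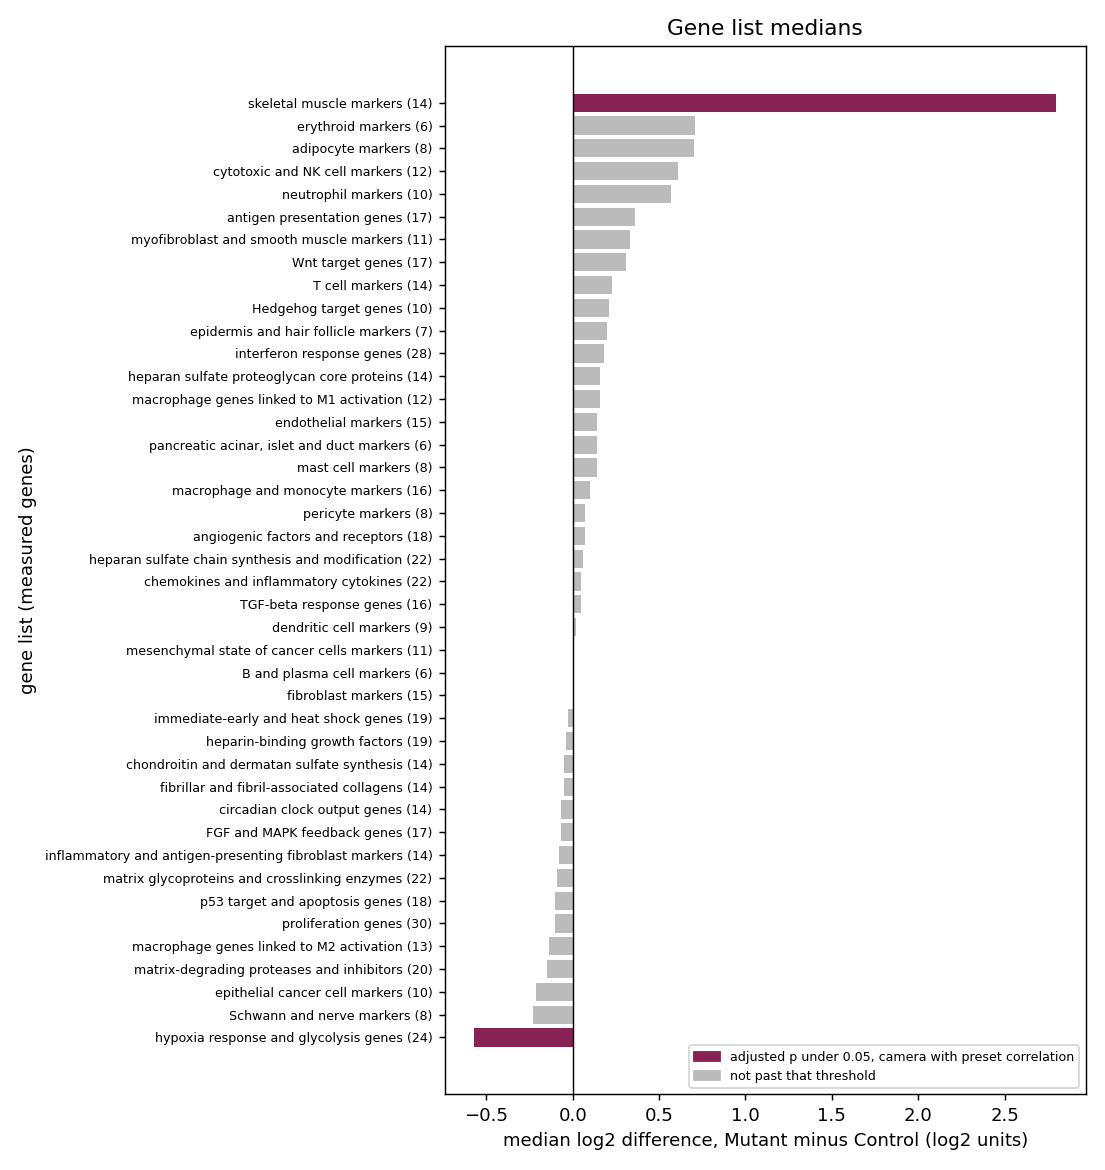
Median log2 difference, Mutant minus Control, of each of the 42 tested gene lists (horizontal axis, log2 units), with the number of measured genes after each name (vertical axis). Dark bars mark the 2 lists with an adjusted p under 0.05 by camera with the preset correlation, skeletal muscle markers at 2.80 and hypoxia response and glycolysis genes at -0.57, and grey bars the others.

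Skeletal muscle genes were the list with the widest difference. Of 14 measured members 13 were higher in Mutant tumours, the median difference was 2.80, and camera called the list (adjusted p = 1.47e-11). The estimated correlation between members was 0.68, and the list was then at an adjusted p = 0.939. Myh4, a myosin heavy chain of fast fibres, differed by 3.99 with a standard error of 1.41, the sarcomere protein Tcap by 2.86, the fast troponin T Tnnt3 by 2.54 and skeletal actin Acta1 by 2.05 (limma adjusted p = 1 for each). Eno3, the muscle enolase, was the exception at -0.38. The per-tumour list level was -0.34, 0.18, -1.68 and -3.14 in Control 1 to 4 and 1.86, 2.59, -0.84 and 1.35 in Mutant 1 to 4, so that 3 of 4 Mutant tumours lay above every Control tumour and Mutant 3 lay within the Control range (two-sided exact permutation p = 0.0857).

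Genes of the hypoxia response and of glycolysis were lower in Mutant tumours in 23 of 24 measured members, with a median difference of -0.57 (camera adjusted p = 1.29e-12). With an estimated correlation of 0.38 the adjusted p was 0.939. Ankrd37, a target of hypoxia-inducible factors, was 0.410-fold, the mitophagy receptor Bnip3 0.427-fold, the collagen prolyl hydroxylase P4ha1 0.654-fold with no overlap of the groups, and the histone demethylase Kdm3a 0.694-fold. Vegfa, the main endothelial growth factor and also a member of the list, was 0.654-fold. None of these genes passed the test over all genes (limma adjusted p = 1 for each). The list level was 0.04, 0.22, 0.69 and 0.13 in Control 1 to 4 and -0.47, -0.37, 0.32 and -0.56 in Mutant 1 to 4 (two-sided exact permutation p = 0.114). The same 3 Mutant tumours that carried more muscle transcript had the lower hypoxia levels. With the muscle list level as a covariate, a setting chosen after the data were seen, the median difference of the hypoxia list was -0.20.

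**Figure D3:**
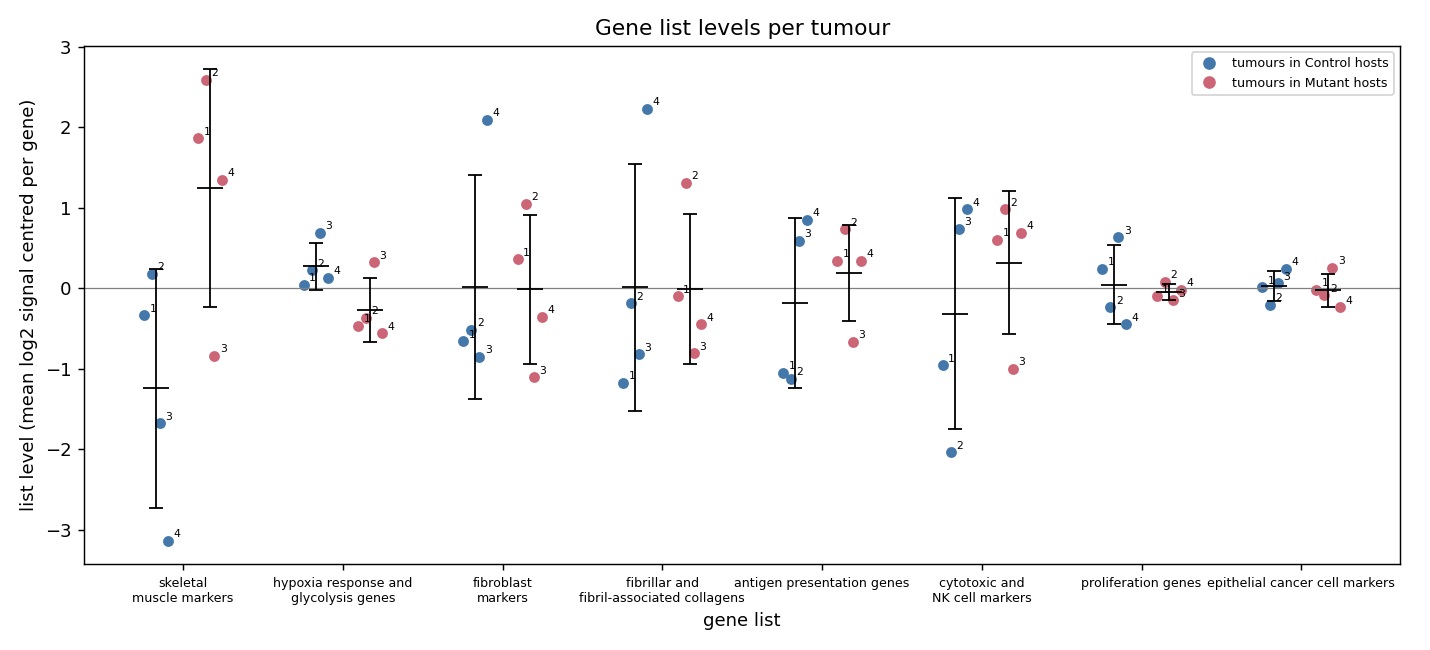
Level of 8 gene lists in each tumour (vertical axis, mean log2 signal over the list after centring each gene on its mean over the 8 tumours). Points are tumours labelled by replicate number, blue for Control and red for Mutant hosts, and black bars give mean and SD (n = 4). Mutant 1, 2 and 4 lie above the Control tumours for skeletal muscle markers and below them for hypoxia genes, and Control 4 lies at 2.09 for fibroblast markers and 2.23 for collagens.

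Fibroblast and matrix genes varied more between tumours of a group than between the groups. The median difference of 15 fibroblast markers was 0.00 (camera adjusted p = 0.866), and that of 14 fibrillar and fibril-associated collagens was -0.05 (adjusted p = 0.596). Control 4 had the highest fibroblast level, 2.09, against -0.85 to -0.52 in the other Control tumours, and Mutant 2 followed at 1.05. Without Control 4 the medians were 0.85 for fibroblast markers and 0.77 for collagens, and camera with the preset correlation called both lists, which it did not with an estimated correlation (adjusted p = 0.58 for both). Without other tumours the medians were as low as -0.47 for fibroblast markers (Mutant 2) and -0.48 for collagens (Control 1), so no direction is stated. Pi16, a marker of adventitial fibroblasts, was 0.261-fold in Mutant tumours (difference -1.94, standard error 0.69, limma adjusted p = 1), while Dpt differed by 1.08 and Pdgfrb by 0.22. Among collagens, Col11a1 differed by 1.65, or 0.62 without Mutant 2, with 3 of 4 Control arrays above background, Col6a1 by -0.31, Col6a2 by -0.42 and Col5a1 by -0.28, the last turning to 0.11 without Control 4. Of 22 matrix glycoproteins and crosslinking enzymes 9 were above 0, with a median of -0.09 (camera adjusted p = 0.445), which was 0.32 without Control 4, 0.06 without Mutant 4, -0.33 without Mutant 2, and -0.26 without Control 3, where the list was called lower at the preset correlation (estimated correlation, adjusted p = 0.896). Plod2, a lysyl hydroxylase that prepares collagen for crosslinking, was 0.648-fold with no overlap of the groups (limma adjusted p = 1). Eln, above background on 2 Control arrays, differed by 1.46, or 0.42 without Control 3, Dcn by 0.54 and Loxl3 by -0.21, and Dcn turned to -0.28 without Control 3.

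Heparan sulfate binds many secreted growth factors, and 19 of these were measured. Their median difference was -0.04 (camera adjusted p = 0.568). Ptn, the heparin-binding factor pleiotrophin, was 8.90-fold higher in Mutant tumours (difference 3.15, standard error 1.08, limma adjusted p = 1). Its level was 4.80, 4.44 and 4.68 in Mutant 1, 2 and 4, but 0.70 in Mutant 3, below Control 3 at 2.66. Vegfa differed by -0.61, Tgfb3 by 0.43 and Igf1 by -0.96. Feedback genes of FGF and MAPK signalling had a median of -0.07 over 17 members (camera adjusted p = 0.231), with Il17rd at 0.64, Dusp4 at -0.71, Spred2 at -0.24 and Etv5 at -0.28. The median was 0.06 without Control 2 or without Mutant 2, and -0.22 without Control 4, where the list was called lower (adjusted p = 0.561 with an estimated correlation). Among 17 Wnt target genes 11 were above 0, with a median of 0.31 (camera adjusted p = 0.0617). The secreted Wnt inhibitor Wif1 was 8.39-fold higher in Mutant tumours, with 3 of 4 Control arrays above background, the Wnt deacylase Notum 1.84-fold, the receptor Lgr5 1.57-fold and the transcription factor Tcf7 1.24-fold (limma adjusted p = 1 for each). Camera with the preset correlation called the Wnt list under 7 of 22 other settings, among them without Control 4 (0.88) and without Mutant 3 (0.63), and its median ranged from 0.10 to 0.88. With an estimated correlation the Wnt list was at an adjusted p = 0.939, and its level differed with a two-sided exact permutation p = 0.543.

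No immune list passed by camera with the preset correlation. All 17 antigen presentation genes were above 0, with a median of 0.36 (camera adjusted p = 0.0617), which ranged from 0.05 to 1.03 over 22 other settings and passed under 11 of them, among them without Control 3, Control 4 or Mutant 3, as it did by ranks (cameraPR adjusted p = 0.00709), but not with its estimated correlation of 0.84 (adjusted p = 0.939). The levels overlapped, with Control 3 at 0.59 and Control 4 at 0.85 above 3 of 4 Mutant tumours or more (two-sided exact permutation p = 0.571). In this list Nlrc5 differed by 0.53, Psmb8 by 0.39, Tap2 by 0.33 and Tapbp by 0.25, and without Control 1 these were 0.18, 0.06, -0.02 and 0.11. Of 12 cytotoxic and NK cell markers 11 were above 0, with a median of 0.61 (camera adjusted p = 0.159), which was -0.09 without Control 2 and was called without Control 3 (0.99), Control 4 (1.08) or Mutant 3 (1.11), but not with an estimated correlation (adjusted p = 0.939; level, two-sided exact permutation p = 0.629). Xcl1 and Gzmk, each above background on 2 Control and 3 Mutant arrays, differed by 1.77 and 1.21, which rests in part on signals not well above background. Gzmb differed by 0.80. Fasl, above background on 3 Control arrays, differed by 0.67, and by -0.02 without Control 2. Neutrophil markers had a median of 0.57 over 10 members (camera adjusted p = 0.0617) and passed under 8 of 22 other settings, among them without Control 1 (0.89), Mutant 1 (0.59) or Mutant 2 (0.68). Without Control 4 it was 0.19, and with an estimated correlation the adjusted p was 0.939 (level, two-sided exact permutation p = 0.143). The collagenase Mmp8 differed by 1.02, Il1r2 by 0.41, S100a9 by 1.10, or 0.19 without Control 4, and Camp by 0.85, or 0.14 without Mutant 4. Macrophage and monocyte markers had a median of 0.10 over 16 members (camera adjusted p = 0.445), with Ly6c2 at 1.01, Cd14 at 0.26, Mertk at 0.30 and Fcgr1 at 0.41. It was -0.05 without Mutant 1 and was called without Control 4 (0.33; adjusted p = 0.58 with an estimated correlation) or Mutant 3 (0.29; 0.974). Genes linked to M2 activation had a median of -0.14 over 13 members (camera adjusted p = 0.212), with Arg1 at -0.92, Chil3 at -1.49, or -0.52 without Control 1, and Msr1 at -0.14, or -0.04 without Control 2. The M2 median was 0.16 without Control 4, and the list was called lower without Control 3 (-0.86; adjusted p = 0.896 with an estimated correlation) or Mutant 2 (-0.44; 0.928). Retnla, above background on 3 arrays of each group, differed by -3.53, or -1.12 without Control 4, and varied widely, as its Control values ran from -7.41 to 6.58.

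As groups, cancer cell, cycling and vessel genes differed little between the groups. Of 10 epithelial cancer cell markers 6 were below 0, with a median of -0.21 (camera adjusted p = 0.231), which was -0.01 without Control 4. The keratins Krt8 and Krt18 were 0.693-fold and 0.722-fold, Cdh1 was 0.566-fold, and Lcn2, an iron-binding lipocalin that inflammation induces, was 3.93-fold higher (limma adjusted p = 1 for each). Without Control 4 the log2 difference was 1.20 in place of 1.98 for Lcn2 and -0.48 in place of -0.82 for Cdh1. Proliferation genes had a median of -0.10 over 30 members, 25 of them below 0 (camera adjusted p = 0.145), and passed under 5 of 22 other settings, among them without Control 2 (-0.20), Control 4 (-0.27) or Mutant 2 (-0.14). It was 0.09 without Control 3, and the adjusted p was 0.0424 by ranks and 0.939 with an estimated correlation. Ccna2 differed by -0.19, Cenpa by -0.25, Foxm1 by -0.24 and Kif11 by -0.20. Endothelial markers had a median of 0.14 over 15 members (camera adjusted p = 0.231), with Egfl7 at 0.30, Emcn at 0.35, Robo4 at 0.28 and Esam at 0.27. The median was 0.00 without Mutant 4, and the list was called without Control 2 (0.43) or Mutant 1 (0.27), with an adjusted p of 0.998 for each at an estimated correlation.

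The leading difference among the tumours was not the host. The first principal component held 45.6% of the variance and set Control 4, at 110.4, against the other tumours, at -34.3 to 42.2 (two-sided exact permutation p = 0.914 between groups). The second held 17.9%, with Mutant 1, 2 and 4 at 35.4 to 38.0, Mutant 3 at -25.2 and the Control tumours at -39.8 to -5.9 (two-sided exact permutation p = 0.0857). Log2 signals of pairs of tumours correlated at 0.926 to 0.991 across genes, which are not independent replicates.

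**Figure D4:**
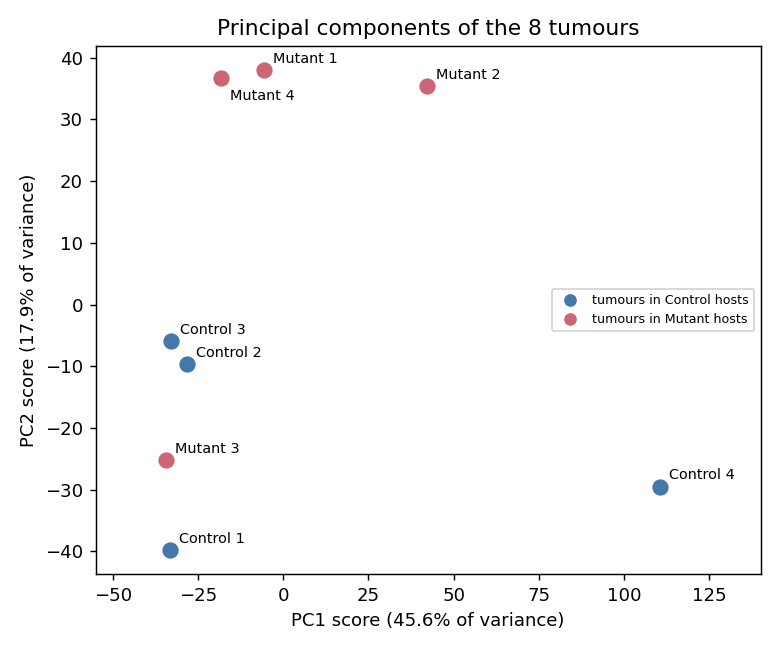
Scores of the 8 tumours on the first (horizontal axis, 45.6% of variance) and second principal component (vertical axis, 17.9%), blue for Control and red for Mutant hosts. Control 4 stands alone at 110.4 on the first component, and Mutant 3 lies at -25.2 among the Control tumours on the second.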

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

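All tests of explanations in this part were chosen after the results were seen. Over both groups, 264 sets of 4 values were searched for a tumour far from the other 3, and 21 were found where chance gives 13.2. Of these, 5 were in Control 4, and Mutant 3 held more.

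In Control 4 the fibroblast level was 2.09 against -0.85 to -0.52 in the other Control tumours, Col18a1 was at 5.16 against 6.10 to 6.22, Col5a1 at 6.50 against 4.80 to 5.06, S100a9 at 1.99 against 5.41 to 5.98, and the first principal component at 110.4. Control 3 stood out in Ptn, at 2.66, and in Bnip3, at 5.72. Mutant 3 stood out in Extl3 (3.88), Extl2 (2.68), Dcn (6.28), Ptn (0.70), Xcl1 (-5.92), Fasl (-4.87) and the second principal component (-25.19). Mutant 2 stood out in the level of Schwann and nerve markers (0.48), Col5a1 (5.62), Eln (-0.46) and P4ha1 (-0.13). Mutant 1 stood out in Cyp2f2 (3.57), and Mutant 4 in S100a4 (7.90) and Emcn (2.04).

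The counts of 2-fold genes and of called lists do not exceed what other groupings of the same tumours give. The real split called 0 genes, a count that all 35 splits of the 8 tumours into 4 and 4 reach by necessity, so it tests nothing, and the highest of the others called 35. At an unadjusted p under 0.05 and at least 2-fold the real split gave 142 genes, 14 of 35 splits gave as many, and the highest other gave 753. The real split called 2 gene lists, 35 of 35 splits called as many, and the highest other called 25, so chance cannot be excluded for the last 2 counts. With an estimated correlation 0 lists were called in any split. The split of Control 1, Control 2, Control 3 and Mutant 3 against the rest called 35 genes. It is the real split with Control 4 and Mutant 3 exchanged and was picked as the largest of the 34 others. Fibroblast levels separated along it, at -1.11 to -0.52 in Control 1, 2, 3 and Mutant 3 and at -0.36 to 2.09 in the rest. The first principal component did so too, at -34.3 to -28.3 against -18.4 to 110.4. The split thus goes with fibroblast transcript, and by itself it is no evidence of exchanged labels, which cannot be checked here. The split along the slide rows called 0 genes and 11 lists and gave 35 genes that differed 2-fold.

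Skeletal muscle markers were higher in 3 of 4 Mutant tumours. Scaling between arrays does not account for this difference, since the lowest median under another background correction or scaling was 1.93. The 75th percentile signals of the arrays lay close together, between 575.9 and 740.7, which left scaling little room to change it. Muscle levels also went with the slide row: the split along the rows gave the list a camera p = 3.46e-13 at the preset correlation. Each row held 2 Control and 2 Mutant tumours, so the row does not coincide with the host. With the row as a block the list was still called higher. Other artefacts of the arrays were not tested. A candidate explanation is skeletal muscle RNA in the sampled tissue: of 26 measured genes of a separate muscle list, written after the pattern was seen, 26 were higher in Mutant tumours, with a median of 2.51, and their level followed the marker list over the 8 tumours (r = 0.99, permutation p = 2.48e-05, adjusted 9.92e-05; rho = 1, the same permutation test, p = 4.96e-05, adjusted 0.000198; r = 0.99 without Control 4 and Mutant 2, and r = 0.99 with the group means removed, permutation p = 0.00174, adjusted 0.00696). Genes of 1 tissue can be expected to move together whatever raised them. The separate list thus shows that the difference spans muscle genes, but it cannot tell the cause. Chance is not excluded, since 4 of 35 splits gave the list as small a camera p (real 6.99e-13, smallest other 8.71e-19). The real split and the split along the slide rows were among them. Whether host genotype bears on how much muscle the tumours contained was not tested.

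Hypoxia and glycolysis genes were lower in the same 3 Mutant tumours, and scaling does not account for it, since the median nearest 0 under another background correction or scaling was -0.54. Muscle RNA could dilute such transcripts: over the 8 tumours the muscle and hypoxia levels had r = -0.76 (permutation p = 0.029, adjusted 0.058) and rho = -0.71 (permutation p = 0.0576, adjusted 0.0768), with r = -0.95 without Control 4 and Mutant 2, but both lists were picked for differing between the groups, and with the group means removed r was -0.55 (permutation p = 0.175, adjusted 0.233) and rho -0.26 (permutation p = 0.554, adjusted 0.739). With the muscle level as a covariate the median was -0.20, which neither removes the shift nor leaves most of it. Dilution of all other transcripts alike is argued against. Levels are centred on each array, so a fall shared by most genes would largely cancel, in this list too. Yet the median difference was -0.57 for the list, against 0.01 over all 16068 genes. Whether muscle content goes with the shift in another way stays open. A lower share of cancer cells cannot be told apart. The hypoxia level minus the epithelial level still differed by -0.49, but with an exact permutation p = 0.0857. The epithelial level is also a mixed measure of this share, with 6 members below 0 and 4 above. Lcn2, which inflammation induces, was at 1.98 and raised it, while the keratins Krt8 and Krt18, at -0.53 and -0.47, fell about as far as the hypoxia list. The proliferation genes do not settle this share. Their median was -0.10, and the hypoxia level differed against theirs by -0.45 (exact permutation p = 0.2). Chance is not excluded, since 2 of 35 splits, the real split among them, gave as small a camera p (real 3.07e-14, smallest other 2.8e-20). The other split exchanges Mutant 3 with Control 1 and so keeps Mutant 1, 2 and 4 together. A biological difference between hosts in oxygen supply or tumour size stays open and untested.

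Control 4 stood apart on the first principal component and held the most fibroblast and collagen transcript. A poor array is argued against, since 67.2% of its probes were well above background, the highest share of the 8 arrays, and its median spot CV of 2.67% lay within the range of the others (2.54% to 2.87%), although its 75th percentile signal was the lowest, 575.9. A large share of whole skin is argued against, since the level of epidermis and hair follicle markers was 0.29 in Control 4, above the other Control tumours (-0.56 to -0.32) but under Mutant 3 (1.85), whose fibroblast level was -1.11. A small share of skin and host connective tissue without epidermis stay open. Y-linked Ddx3y was above background only in tumours without Xist signal, so host cells, not the shared cancer cell line, are its likely source. It was at -2.57 in Control 4, against -4.01 in Control 1, -3.54 in Mutant 2 and -4.58 in Mutant 3. This goes with more host cells in Control 4, but it rests on few tumours. No biological explanation was tested, and the labels give nothing that sets Control 4 apart.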

How the results depend on the processing

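Under 26 alternative settings, of which the Xist and muscle covariates were chosen after the data were seen, limma called 0 genes higher and 0 lower wherever genes were tested, with 371 genes at an unadjusted p under 0.05 under the replicate block and 1280 with array weights, and with a smallest adjusted p of 0.365, without Control 2. The count at an unadjusted p under 0.05 and at least 2-fold, 142, was 88 with normexp, 227 with no filter, 83 with probes above background on all 8 arrays, 249 over single probes, 404 with array weights and 65 with the muscle level as a covariate, and 50 to 249 with a tumour left out. Fewer or more probes were tested under the filters and the probe-wise test; the cause was not tested for the others. The count of lists called, 2, was 5 with normexp, 3 with quantile normalization, 4 with median centring, 6 with no filter, 4 with probes above background on all arrays, 6 with the mean of a gene's probes, 9 with array weights, 9 with the muscle covariate, 0 with an estimated correlation, 0 by fry and 4 by ranks, and 2 to 20 with a tumour left out; the cause was not tested. The hypoxia list, at -0.57, and the muscle list, at 2.80, kept their direction and call wherever they could be tested, except with the estimated correlation (adjusted p = 0.939 for both) and fry (0.993 for both), which allow for the correlation of their members. Their medians ranged from -0.65 to -0.41 and from 1.99 to 3.48 with a tumour left out, and the muscle covariate, which is the level of the muscle list itself, left that list at 0.10 and not called (adjusted p = 0.952), by construction. With the replicate block 0 genes and 6 lists were called. The values gave no sign that the numbers pair the tumours. Deviations of same-numbered tumours from their group means correlated at -0.31 to 0.08, and 0 Control tumours correlated best with their own number. With 4 tumours per group this cannot exclude a pairing by design.

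Ext1, at 0.07, turned to -0.11 with array weights and to -0.23 with the muscle covariate, and ranged from -0.28 to 0.26 with a tumour left out, while S100a4 kept its direction (0.05 to 0.41). Of 1938 alternative values of the 85 named genes other than these, 1929 kept direction and side and 9 turned, in 7 genes. With the muscle covariate Col18a1 was -0.10, Gpc2 -0.13, Pdgfrb -0.11 and Col5a1 0.07, and with array weights Col5a1 was 0.00. With a tumour left out, Col5a1 ranged from -0.47 to 0.11, Dcn from -0.28 to 0.92, Tap2 from -0.02 to 0.59 and Fasl from -0.02 to 1.10. In 51 of the 85 genes leaving out a tumour moved the log2 difference by over 1.5 times or turned it. The cause was not tested. The deposited value table differs from the scanner signals by so little that its agreement says nothing about stability. Signal over background limits Mmp7 to a bound and leaves Gp9, Shisa2, Xcl1, Gzmk and Eln measured on part of the arrays.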

Other observations

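In this part the Xist covariate and the relations between levels were chosen after the data were seen, while the lists were fixed before. Other tissue and cell type lists also varied between tumours. Adipocyte markers had a median difference of 0.70 over 8 genes (camera adjusted p = 0.212), with the highest level in Mutant 2, at 1.74. Erythroid markers had 0.71 over 6 (0.231), myofibroblast and smooth muscle markers 0.33 over 11 (0.159), and Schwann and nerve markers -0.23 over 8 (0.212), with Control 4 at 1.86. Epidermis and hair follicle markers had 0.20 over 7 genes (0.354) and were highest in Mutant 3, at 1.85. T cell markers had a median of 0.23 over 14 genes (0.647), B and plasma cell markers 0.01 over 6 (0.879), dendritic cell markers 0.02 over 9 (0.879) and mast cell markers 0.14 over 8 (0.825). T cell levels were highest in Control 4, at 1.56, and lowest in Control 2, at -1.65. Pericyte markers had 0.07 over 8 (0.879), inflammatory and antigen-presenting fibroblast markers -0.08 over 14 (0.825), where the mean was 0.26 and the test pointed up, markers of a mesenchymal state of cancer cells 0.01 over 11 (0.879), and pancreatic acinar, islet and duct markers 0.14 over 6 (0.557). Levels of the pancreatic list did not overlap between the groups (two-sided exact permutation p = 0.0286, adjusted 0.857 over the lists). Values in parentheses after the first are camera adjusted p too. Leaving out a tumour turned the median for T cell (-0.28 without Control 2, 0.81 without Control 4), Schwann (-0.43 without Control 3, 0.17 without Control 4), mast cell (-0.33 without Control 3, 0.63 without Control 4), B cell (-0.22 to 0.33), dendritic (-0.07 to 0.39), pericyte (-0.14 to 0.26), inflammatory fibroblast (-0.21 to 0.25), mesenchymal (-0.13 to 0.38), epidermis (-0.04 to 0.68) and pancreatic markers (-0.01 to 0.23). It moved the median from 0.04 without Control 1 to 1.21 without Mutant 1 for erythroid, from 0.16 without Mutant 2 to 0.92 without Control 4 for adipocyte and from 0.16 to 0.66 for myofibroblast markers.

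Among pathways, interferon response genes had a median of 0.18 over 28 genes (camera adjusted p = 0.212), and their level ran from -1.52 in Control 1 to 1.23 in Control 3. Hedgehog target genes had 0.21 over 10 (0.232), genes of chondroitin and dermatan sulfate synthesis -0.05 over 14 (0.866), matrix-degrading proteases and inhibitors -0.15 over 20 (0.809), and angiogenic factors and receptors 0.07 over 18 (0.866), where the test pointed down. TGF-beta response genes had 0.05 over 16 (0.891) and chemokines and inflammatory cytokines 0.05 over 22 (0.774), both with a test that pointed down. Genes linked to M1 activation of macrophages had 0.16 over 12 (0.866), p53 target and apoptosis genes -0.10 over 18 (0.292), immediate-early and heat shock genes -0.03 over 19 (0.354), and circadian clock output genes -0.07 over 14 (0.866). Over 22 other settings, camera with the preset correlation called the erythroid list 5 times, the interferon list 4, the T cell, adipocyte and myofibroblast lists 3 each, the mast cell list 2, and the chondroitin, protease, inflammatory fibroblast, dendritic, epidermis, Schwann and mesenchymal lists 1 each, none of them with an estimated correlation. With a tumour left out, medians ranged from -0.10 to 0.69 for interferon, 0.04 to 0.33 for Hedgehog, -0.24 to 0.23 for chondroitin, -0.38 to 0.19 for protease, -0.11 to 0.19 for angiogenic, -0.10 to 0.15 for TGF-beta, -0.12 to 0.27 for chemokine, -0.03 to 0.36 for M1, -0.16 to 0.00 for p53, -0.17 to 0.06 for immediate-early and -0.11 to 0.05 for clock genes. In the same settings 0 calls were made of the Hedgehog, TGF-beta, angiogenic, chemokine, M1, p53, immediate-early and clock lists.

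Xist, the RNA of the inactive X chromosome, was above background in Control 2, Control 3, Mutant 1 and Mutant 4, at -2.89, -2.83, -2.22 and -2.70, and not in the other tumours. Y-linked Ddx3y was above background in those others, at -4.01 in Control 1, -2.57 in Control 4, -3.54 in Mutant 2 and -4.58 in Mutant 3. Each group thus held 2 tumours of either kind. Since the cancer cell line is shared, this goes with hosts of both sexes in each group, but the labels used here do not give host sex. With the Xist level as a covariate limma called 0 genes, 502 were at an unadjusted p under 0.05, and camera called 2 lists.

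The muscle level was also set against Mmp7 and the epithelial level over the 8 tumours, 4 relations in all with those given above. For Mmp7, r was 0.70 (permutation p = 0.0589, adjusted 0.0589) and rho 0.67 (permutation p = 0.0831, adjusted 0.0831), and r was 0.69 without Control 4 and Mutant 2, but with the group means removed r was 0.21 (permutation p = 0.677, adjusted 0.677) and rho 0.12 (permutation p = 0.806, adjusted 0.806), so the relation rests on the difference between the groups. For the epithelial level, r was -0.69 (permutation p = 0.0572, adjusted 0.0589) and rho -0.74 (permutation p = 0.0458, adjusted 0.0768), and r was -0.57 without Control 4 and Mutant 2. With the group means removed r was -0.84 (permutation p = 0.0295, adjusted 0.059) and rho -0.86 (permutation p = 0.0208, adjusted 0.0416). Over the 8 tumours as they are, neither relation passed the adjustment.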
